A study of Homo sapiens with 17 samples.

How the data were processed

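The data are 17 samples of MCF-7, an estrogen-dependent human breast cancer cell line, each hybridised to 1 Affymetrix array with 22283 probe sets. Per the labels, cells were infected with a control adenovirus (Ad) or an adenovirus carrying estrogen receptor beta (AdERb). They then received vehicle, 10 nM 17beta-estradiol (E2) or 10 nM trans-hydroxytamoxifen (TOT, an active tamoxifen metabolite) for 24 h, and the infection preceded the ligand by 48 h. The groups were Ad with vehicle (2 arrays), and Ad with E2, Ad with TOT, AdERb with vehicle, AdERb with E2 and AdERb with TOT (3 arrays each). The sample descriptions give a multiplicity of infection of 10, while the extraction protocol gives 5 or 50, so the dose of virus is not settled by the labels. The protocols describe growth in medium with 5% charcoal-dextran-stripped calf serum in 100 mm dishes, RNA extracted with TRIzol, and about 8 µg of total RNA made into biotin-labelled cRNA. The letter b stands in the titles of 4 arrays, both of Ad with vehicle and replicates 1 and 2 of Ad with E2. The labels do not say what it means.

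Per the submitters' processing notes, the authors computed the deposited intensity values from the scanned arrays with GCRMA. Its version and any scaling after it are not stated. The deposited intensities were read as linear from the values themselves: none is negative, array medians lie between 7.4 and 9.18 and array maxima between 13926 and 19450. They were taken to the log2 scale before any test, with no added constant. The number of arrays limits the precision. Of the probe sets, 68 are array controls, 19065 of the others have 1 gene symbol in the platform's annotation, 1043 have several, and 2107 are unnamed here. For 19053, the symbol was updated through the Entrez gene number to a RefSeq gene table of assembly GRCh38.p14, used for names only.

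Probe sets were kept if they were no control and lay above their array's own median on at least 2 arrays, which left 12721, of which 11073 have 1 symbol and stand for 7772 genes. A gene was represented by its kept probe set with the highest mean over all arrays. PGR and other genes without such a probe set are not analysed here. All 17 arrays entered 1 limma fit (version 3.58.1 in R 4.3.3) with a mean per group and a variance prior that follows the mean. The groups share 1 estimate of the spread. Leaving out an array of a group outside a contrast therefore changes its p-values but not its log2 change. Adjusted p-values are limma's, with Benjamini-Hochberg adjustment over the probe sets kept, and the threshold is 0.05. In the report, a log2 change stands with its standard error (SE) from that fit, and a mean of a group with its standard deviation (SD). A gene "rose" or "fell" only if its adjusted p passed. The 11 contrasts were each ligand against vehicle and TOT against E2 in either cells, AdERb against Ad under each of the 3 conditions, and the difference of each ligand's effect between AdERb and Ad cells.

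A set of 20 gene lists was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 20 lists within a contrast. The estimated correlation was used beside it. The lists were estrogen-induced genes, estrogen-repressed genes, DNA replication and G1/S genes, mitosis genes, p53 target genes, interferon-stimulated genes, sterol biosynthesis and uptake genes, fatty acid synthesis genes, unfolded protein and integrated stress response genes, ribosome biogenesis genes, NRF2 target genes, aryl hydrocarbon receptor target genes, luminal epithelial identity genes, basal and mesenchymal markers, fibroblast markers, leukocyte markers, TGF-beta target genes, actin cytoskeleton and adhesion genes, apoptosis regulators, and nuclear receptors and coregulators. TOT-preferential genes passed in TOT against vehicle and in TOT against E2 with the same sign, and E2-preferential genes passed in E2 against vehicle and in E2 against TOT with the same sign.

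Named genes follow a fixed rule. For each contrast of a pair of groups it takes, among genes past the threshold whose single arrays do not overlap between the groups, the 10 largest rises and the 10 largest falls. It adds up to 4 members of each list past the threshold, or 2 where none passed, and 7 genes in any case (ESR1, ESR2, PGR, TFF1, GREB1, CCND1 and MYC). For the difference contrasts and for the ligand-preferential genes it takes the 10 largest in each direction. The text gives mostly those of them that stayed past the threshold with each array left out, and for others the arrays whose omission ends the call. The contrasts, lists, tests, named-gene rule and most alternatives were fixed before the data were examined.

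Alternatives were no filter on level, a stricter filter at the 75th percentile, no trend in the variance prior, estimated array weights, the replicate number as a block, the letter b as a covariate, only the arrays of the cells compared, an offset of 16 before log2, quantile normalization, a minimum of 1.5-fold, a gene's other probe sets, the mean over a gene's probe sets, the estimated correlation, and each array left out in turn. Chosen after seeing the data were the spike-in level as a covariate, leaving out both AdERb E2 replicate 3 and AdERb TOT replicate 3, comparisons within arrays that share or lack the letter b, and probe sets with a mean above 6 on the log2 scale.

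The replicate numbers were checked for pairing by the correlation of the deviations of same-numbered arrays from their group means. Nothing in the labels says that a number marks a shared day or culture. Only for AdERb against Ad with E2 were all the correlations above 0.1, at 0.254, 0.133 and 0.439. The blocked result is therefore given beside that contrast.

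The steps were tested on simulated data, with 200 changed probe sets among 12721. At a log2 change of 1 and of 2, the share recovered was 56% and 87% for E2 against vehicle in Ad cells, 60% and 89% for TOT against vehicle in Ad cells, 62% and 96% for E2 against vehicle in AdERb cells, and 66% and 95% for TOT against vehicle in AdERb cells. For AdERb against Ad it was 56% and 96% with vehicle, 62% and 94% with E2, and 53% and 94% with TOT. For the difference of the E2 effect it was 30% and 81%, and for that of the TOT effect 28% and 73%. These shares hold for the simulated noise only, so they need not hold where an array stands apart from its group. In the data, 0 probe sets passed for E2 against vehicle in AdERb cells. There RRM2 at 3.27 and PTTG1 at 2.72 did not pass in limma (adjusted p 0.543 and 0.374). In simulated TOT against vehicle in Ad cells, the list test called 1 of 20 lists, the one that had been shifted. The simulated noise was independent between genes, so it cannot show false calls on lists whose genes move together. In the data the estimated correlation was 0.462 for the mitosis list, and 47 of 55 list calls were lost with estimated correlations.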

Results

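RNA of MCF-7 breast cancer cells was measured on 17 arrays in 6 groups. Cells carried either the control virus (Ad) or the virus for estrogen receptor beta (AdERb), and had received vehicle, E2 or TOT. Ad with vehicle has 2 arrays and the other groups have 3 each. The series asks which genes tamoxifen regulates preferentially, and the viruses add the question of how estrogen receptor beta changes the response to either ligand. Nothing in the labels says that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical. Both Ad vehicle arrays carry the unexplained letter b and no Ad TOT or AdERb vehicle array does. TOT against vehicle in Ad cells, and AdERb against Ad with vehicle, therefore differ in that letter too. Its effect can be estimated only through Ad E2, where 1 array lacks it. That array, Ad E2 3, correlated with Ad E2 1 and 2 at an r of 0.97 and 0.974, and they with each other at 0.991. An effect of the letter therefore cannot be told apart from other traits of that array.

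ESR2, the gene carried by AdERb, lay at background in Ad cells, with a GCRMA intensity of 5.88 ± 0.336 (SD, n = 2) with vehicle, 6.0 ± 0.645 (n = 3) with E2 and 5.60 ± 0.0433 (n = 3) with TOT. In AdERb cells it reached 2120 ± 276 with vehicle, 4786 ± 4241 with E2 and 4779 ± 2751 with TOT (n = 3 each), so every AdERb array stood far above every Ad array. Its log2 rise with vehicle was at least 8.48 ± 0.54 (SE; adjusted p 1.28e-06), a lower bound because the Ad values lay below the array medians of 7.4 to 8.26. ESR1, the gene of estrogen receptor alpha, was measured in all groups, with 1675 ± 131 in Ad vehicle cells and 1194 ± 193 in AdERb vehicle cells, a difference that did not pass (adjusted p 0.864).

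**Figure D1:**
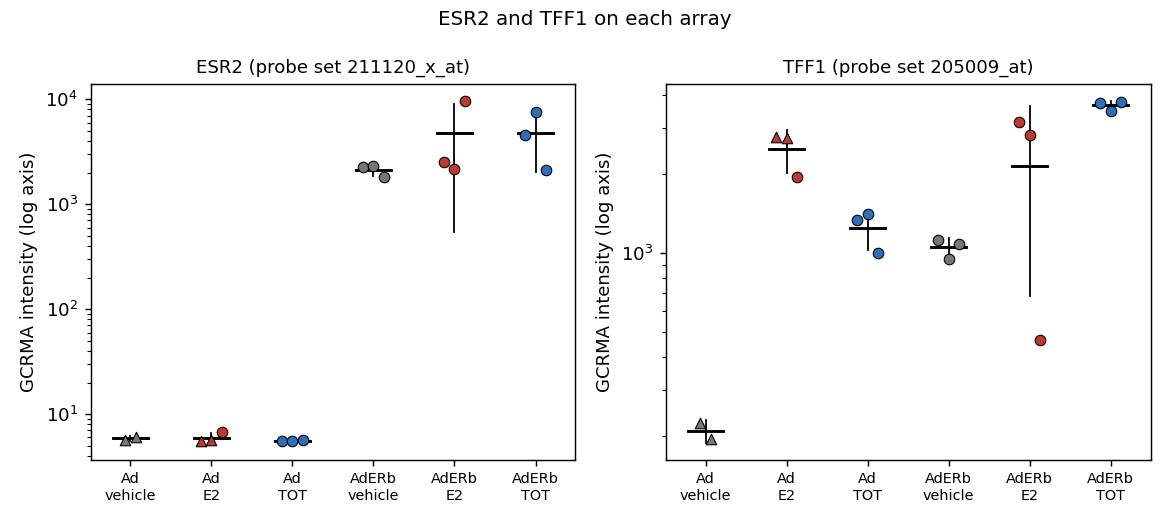
GCRMA intensity of ESR2 and TFF1 on a log axis for the 6 groups, with a point per array (triangles carry the letter b), a bar at the mean and a line for ± 1 SD. ESR2 lies near 5.88 in Ad vehicle cells and at 2120 in AdERb vehicle cells, and TFF1 rises from 209 to 2480 with E2 in Ad cells.

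E2 in Ad cells raised the estrogen-response gene TFF1 from 209 ± 20.8 (SD, n = 2) to 2480 ± 466 (n = 3), a log2 rise of 3.55 ± 0.55 (SE; adjusted p 0.00197). Among the rises that held with each array left out were genes of DNA synthesis and cell division: PRIM1, a DNA primase subunit, rose by 4.25 ± 0.47, the mitotic kinesin KIF2C by 3.98 ± 0.31, KIF4A by 3.87 ± 0.32, the spindle factor TPX2 by 3.81 ± 0.40 and thymidine kinase TK1 by 2.74 ± 0.36, with adjusted p-values of at most 0.000482. Among falls, the transcription factor partner ARNT2 changed by -1.93 ± 0.19, KLF6 by -1.87 ± 0.20, the phosphatase DUSP2 by -1.87 ± 0.28, the pro-apoptotic BAK1 by -1.93 ± 0.29 and CRIP2 by -2.56 ± 0.37. MYC rose by 2.12 ± 0.49 (adjusted p 0.0335), but without any of Ad vehicle 1 or 2, Ad E2 1 or 2, Ad TOT 2 or AdERb vehicle 3 it did not pass, with an adjusted p of up to 0.204, nor with no filter on level. ASNS, asparagine synthetase, rose by 3.01 ± 0.55 and did not pass without Ad vehicle 2 (0.128). GREB1 (1.87, adjusted p 0.0521), ESR1 (-0.57, 0.363) and CCND1 (-0.26, 1) did not pass, but GREB1 did without Ad E2 3 (2.59, 9.31e-06), AdERb E2 3 (0.0454) or AdERb TOT 3 (0.0489), and CCND1 was 0.016 without Ad E2 3.

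The mitosis list rose with E2 as a whole, with a median log2 change of 2.62 over 36 genes. Of these, 26 passed over all genes and 36 when adjusted over the list alone (camera adjusted p 2.26e-54, and 0.0196 with the estimated correlation). DNA replication and G1/S genes rose by a median of 1.65 over 33 genes, 15 past over all genes and 27 adjusted over the list alone (1.91e-25, and 0.0361 with the estimated correlation). In brackets after a list stand the adjusted p with the preset correlation and that with the estimated correlation. For pairs of counts, the former is over all genes and the latter adjusted over the list alone. The next lists passed only with the preset correlation. Estrogen-induced genes had a median of 1.03 over 31 genes, with 5 risen over all genes and 15 adjusted over the list alone (9.5e-11, estimated 0.147). Estrogen-repressed genes had a median of -0.69 over 12, with 2 fallen over all genes, and 4 fallen and 1 risen adjusted over the list alone (0.000276, estimated 0.239). Unfolded protein and integrated stress response genes had 0.36 over 22, with 3 and 5 risen (0.000608, estimated 0.382). Ribosome biogenesis genes had 0.77 over 15 with none past on its own (0.000338, estimated 0.342), and TGF-beta target genes -0.38 over 10, with 1 and 4 fallen (0.000371, estimated 0.147).

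The remaining lists did not pass with E2 in Ad cells. Their medians were 0.07 for p53 target genes (adjusted p 0.995), 0.01 for interferon-stimulated genes (0.938), 0.11 for sterol biosynthesis and uptake genes (0.512), -0.01 for fatty acid synthesis genes (0.986), 0.14 for NRF2 target genes (0.607) and 0.06 for aryl hydrocarbon receptor target genes (0.973). They were -0.15 for luminal epithelial identity genes (0.143), 0.13 for basal and mesenchymal markers (0.283), -0.01 for fibroblast markers (0.938), -0.02 for leukocyte markers (0.938), -0.002 for actin cytoskeleton and adhesion genes (0.938), 0.05 for apoptosis regulators (0.995) and -0.03 for nuclear receptors and coregulators (0.973). No list past the threshold in any of the 11 contrasts had a median, mean and test that differed in sign. Among lists that did not pass, p53 target genes here had a positive median and a test that pointed down. Interferon-stimulated, sterol, fatty acid, NRF2, aryl hydrocarbon receptor, fibroblast, leukocyte, apoptosis and nuclear receptor lists passed in 0 of 11 contrasts.

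In total, E2 changed 295 of 12721 probe sets in Ad cells, 218 up and 77 down, which stand for 204 genes, and 13 of 33 named genes past the threshold stayed past it with each array left out. The count rested on single arrays: it was 132 without Ad vehicle 1, 114 without Ad vehicle 2, 132 without Ad E2 1, 124 without Ad E2 2, 762 without Ad E2 3 and 453 without AdERb E2 3.

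TOT in Ad cells also raised genes of DNA synthesis and cell division, while the ribosome biogenesis list did not pass (median 0.048, camera adjusted p 0.878). KIF2C rose by 4.31 ± 0.31 (SE), KIF4A by 4.04 ± 0.32, TPX2 by 3.998 ± 0.402, the transcription factor FOXM1 by 3.75 ± 0.43, PRIM1 by 3.40 ± 0.47, the replication helicase subunit MCM5 by 3.25 ± 0.43 and TK1 by 3.07 ± 0.36, all with adjusted p-values of at most 0.000579 and past the threshold with each array left out. The chemokine receptor ACKR3 changed by -2.04 ± 0.18, the apoptosis repressor NOL3 by -2.55 ± 0.27, the stress-response gene NDRG1 by -2.08 ± 0.32, and BAK1 by -2.04 ± 0.29. TFF1 rose to 1243 ± 216 (SD, n = 3), by a log2 change of 2.56 ± 0.55 (SE; adjusted p 0.0166), which did not pass without any of Ad vehicle 1 or 2 or Ad TOT 1 or 2 (up to 0.129) or with the letter b as a covariate. IGFBP4 rose by 4.13 and AGR2 by 1.01, and neither passed without Ad vehicle 2 (0.124 and 0.0862) or with the letter b as a covariate. MYC (0.20, adjusted p 0.969), GREB1 (-0.08, 0.978), CCND1 (0.39, 0.969) and ESR1 (-0.57, 0.462) did not pass. GREB1 turned to 2.10 with the letter b as a covariate, where the effect of the letter rests on Ad E2 3 alone.

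Mitosis genes rose with TOT by a median of 3.08, with 33 of 36 past over all genes and 36 adjusted over the list alone (1.31e-73, estimated 0.0059). Replication genes rose by 1.86, with 20 and 29 of 33 (4.21e-35, estimated 0.0116). Estrogen-induced genes had a median of 0.84, with 9 and 13 of 31 (3.44e-09, estimated 0.279). Estrogen-repressed genes had -0.83 (0.00542, estimated 0.463), unfolded protein and integrated stress response genes 0.33 (0.0432, estimated 0.751) and TGF-beta target genes -0.23 (0.027, estimated 0.463). Adjusted over the list alone, the repressed list had 2 genes risen and 4 fallen, and TGF-beta targets 2 fallen.

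TOT changed 394 probe sets in Ad cells, 312 up and 82 down, for 264 genes, and 14 of 33 named genes held with each array left out. With the letter b as a covariate it changed 498, 451 up and 47 down, of which 245 are among the 394. The count was 201 without Ad vehicle 1, 212 without Ad vehicle 2 and 227 without Ad TOT 2. E2 and TOT changed 98 genes up and 25 down together, where independent lists would share 4.11 and 0.366. Both contrasts use the same vehicle arrays. Across the 12721 probe sets, which are not independent replicates, their log2 changes correlated with an r of 0.762, while simulated unchanged groups gave a mean of 0.544 and a 95% range from -0.195 to 0.91. The covariance was 0.2046, against a simulated mean of 0.0625 and a range from -0.0122 to 0.1939. The r lay inside its simulated range and the covariance just above its own. The 2 vehicle arrays were not split, as that leaves 1 for each ligand, so part of both may come from the shared controls.

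**Figure D2:**
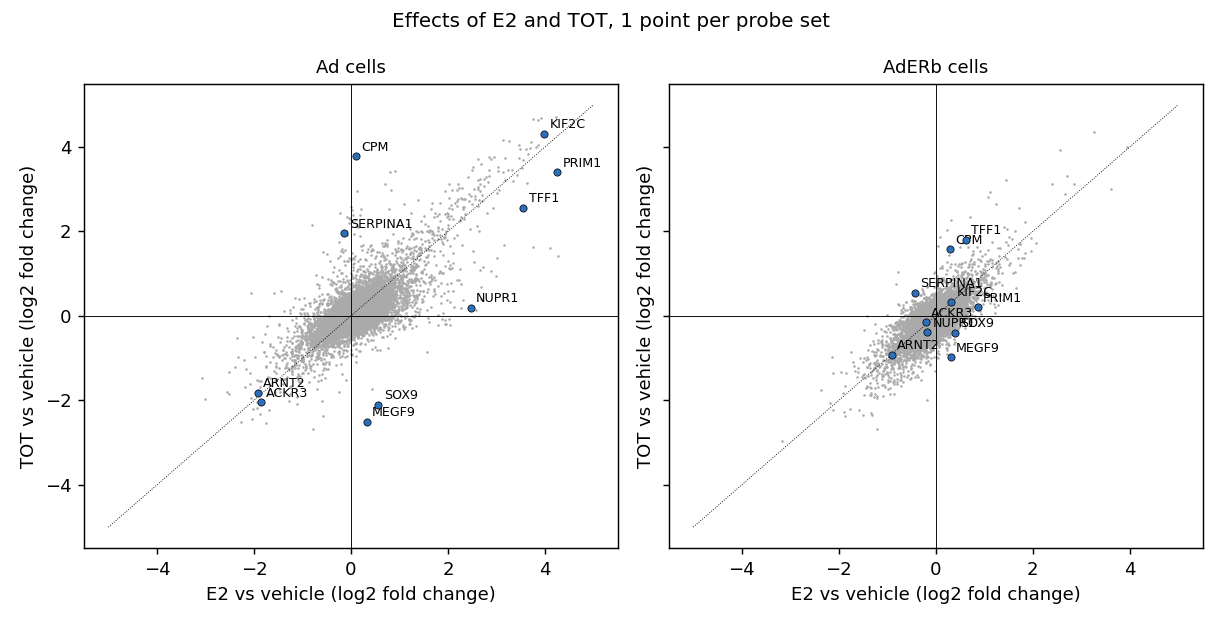
Log2 change with TOT against that with E2, each relative to vehicle, with a point per probe set and some named genes marked; the dotted line is equality. In Ad cells r is 0.762 and CPM lies at 3.78 on the TOT axis, while in AdERb cells r is 0.781 and the points lie closer to 0.

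The direct comparison of TOT with E2 in Ad cells addresses preferential regulation. The protease inhibitor SERPINA1 was higher with TOT by 2.09 ± 0.22 (SE), with log2 means of 6.74 ± 0.02 (SD) against 4.65 ± 0.08 (n = 3 each; adjusted p 0.000226). The ligand EFNB2 was higher by 1.95 ± 0.21, the phosphatase PTPRG by 1.96 ± 0.23, SNX24 by 2.20 ± 0.30 and the scaffold protein NHERF1 by 2 ± 0.30. CPM, carboxypeptidase M, was higher by 3.67 ± 0.31 (2.76e-05) on its brightest probe set, while its other probe set gave -0.12, so its direction is not settled. Lower with TOT were the membrane protein MEGF9 by -2.83 ± 0.41, the stress gene NUPR1 by -2.27 ± 0.31, the mitochondrial enzyme PCK2 by -2.05 ± 0.27 and the transcription factor SOX9 by -2.66 ± 0.44 (adjusted p 0.00753, lost with the letter b as a covariate, where the E2 side rests on Ad E2 3 alone). GREB1 differed by -1.94 ± 0.42 (0.0419), but with TOT it lay at background, at 8.22 ± 0.388 (SD, n = 3) as with vehicle (8.68 ± 0.810, n = 2), so the size is not exact. Its call was lost with 13 of the 17 arrays left out, all but Ad E2 3, AdERb E2 3, AdERb TOT 2 and AdERb TOT 3, with an adjusted p of up to 0.211, and with 7 other settings, the letter b as a covariate and only the arrays compared among them. TFF1 (-0.99, adjusted p 0.629) and MYC (-1.92, 0.0544) did not pass. Without AdERb E2 3 both passed (0.00679 and 0.0103), and MYC also without Ad E2 3 (0.029), AdERb E2 2 (0.0317), AdERb TOT 2 (0.0402) or AdERb TOT 3 (0.0353). The AdERb arrays are not in this contrast, so their omission changed the shared spread and not the log2 changes.

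Ribosome biogenesis genes were lower with TOT than with E2 (median -0.65, 1 of 15 past adjusted over the list alone; 2.85e-05, estimated 0.455), and mitosis genes higher (0.42, 1 past over all genes and 3 adjusted over the list alone; 1.86e-05, estimated 0.632). The p53 target genes (-0.29; 0.011, estimated 0.455) and basal and mesenchymal markers (-0.21; 0.0263, estimated 0.455) were also lower. In total 116 probe sets differed, 73 higher and 43 lower with TOT. This balance is not settled: it was 69 higher and 217 lower without Ad E2 3, 106 and 113 with the spike-in level as a covariate, and 109 and 13 with the letter b as a covariate, where only 42 of the 122 probe sets are among the 116. Of genes, 41 were TOT-preferential (35 up, 6 down), 17 were E2-preferential (13 up, 4 down) and 123 changed the same way with both. Simulated unchanged groups were made by shuffling the residuals of all 17 arrays over the groups, so their spread is not that of the Ad arrays alone. They gave a median of 0 for each class over 100 draws, but 1 draw gave 917 TOT-preferential genes and 1 draw 936 changed the same way. The 41 became 20 without either Ad vehicle array, 26 without Ad E2 2, 27 without Ad TOT 1 and 19 without Ad TOT 2. The 17 became 118 without Ad E2 3, 33 without AdERb E2 3, 32 without AdERb TOT 3, and between 3 and 11 without any of Ad vehicle 1 and 2, Ad E2 1 and 2, Ad TOT 1 to 3, AdERb vehicle 1 to 3 and AdERb E2 1. The 123 became 70 without Ad vehicle 1, 62 without Ad vehicle 2, 69 without Ad E2 1 or Ad E2 2, 208 without Ad E2 3 and 186 without AdERb E2 3. Of 38 named genes past the threshold, 10 held with each array left out. The 116 became 61 without Ad E2 2, 286 without Ad E2 3, 54 without Ad TOT 1, 41 without Ad TOT 2, 73 without Ad TOT 3 and 193 without AdERb TOT 3.

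AdERb against Ad cells with vehicle asks what the receptor's virus changes without ligand, in groups that differ in the letter b too. Apart from ESR2, ACTG2, a smooth-muscle actin, rose from 21.9 ± 7.40 (SD, n = 2) to 787 ± 229 (n = 3), by 5.16 ± 0.86 (SE; adjusted p 0.0257), which did not pass without any of Ad vehicle 1 or 2 or AdERb vehicle 1 or 2 (up to 0.133), or with the letter b or the spike-in level as a covariate or the replicate block. MYLK, myosin light chain kinase, rose by at least 2.89 ± 0.38, from a background value of 7.20 ± 0.518 (SD, n = 2) in Ad cells, but not past the threshold without Ad vehicle 1 (0.0553). ACKR3 changed by -1.85 ± 0.18 and the fibrillin FBN2 by -1.24 ± 0.14, both past the threshold with each array left out but not with only the arrays compared. KLF6 fell by 1.47 and CSTA by 1.92, calls lost without Ad vehicle 1 (0.0805) and Ad vehicle 2 (0.0692). MYLK, CSTA and KLF6 also lost their calls with only the arrays compared, and MYLK and CSTA with the letter b as a covariate. TFF1 was 1050 ± 88.9 in AdERb against 209 ± 20.8 in Ad cells, a log2 difference of 2.33 that did not pass (adjusted p 0.151). Among arrays left out, it passed only without AdERb E2 3 (1.02e-05). That array is not in this contrast, so the 2.33 stayed and only the shared spread changed. The log2 SD of TFF1 was 1.55 in AdERb E2 cells, against 0.143 in Ad and 0.125 in AdERb vehicle cells.

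The p53 target genes were higher in AdERb vehicle cells, with a median of 0.58, 0 of 17 past over all genes and 3 adjusted over the list alone (8.41e-08, estimated 0.0349). CDKN1A, a p53 target that blocks the cell cycle, was at 1.41 and did not pass (adjusted p 0.0788), except without AdERb E2 3 (0.0245) or AdERb TOT 3 (0.0488) among arrays left out. Estrogen-induced genes were higher (0.23; 4.5e-05, estimated 0.401), as were actin cytoskeleton and adhesion genes (0.34; 7.12e-05, estimated 0.181). Mitosis genes were lower (-0.24; 8.41e-08, estimated 0.401) and replication genes too (-0.26; 0.0106, estimated 0.764), but with the letter b as a covariate their medians turned to 0.50 and 0.60, so these directions are not settled. Adjusted over the list alone, the estrogen-induced list had 2 genes, the actin list 1, mitosis 8 and replication 1 past the threshold. Over all genes, RRM2 (-3.30), PTTG1 (-3.57) and UBE2C (-2.88) passed only without AdERb E2 3 among arrays left out, with limma adjusted p-values of at most 0.000159. Of the probe sets 15 passed, 5 up and 10 down, and 3 of 11 named genes held with each array left out. The count was 34 without Ad vehicle 2, 33 without AdERb vehicle 2, 43 without AdERb E2 3 and 41 without AdERb TOT 3. After quantile normalization 51 passed, 51% of them up against 33.3% before.

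With E2, single genes of cell division were lower in AdERb than in Ad cells, while the mitosis and replication lists passed only with the preset correlation (estimated adjusted p 0.0506 and 0.114). KIF20A changed by -4.22 ± 0.33 (SE), DNA topoisomerase TOP2A by -3.93 ± 0.47, KIF2C by -3.83 ± 0.28, FOXM1 by -3.66 ± 0.38, CDCA8 by -3.63 ± 0.19 and the chromatin protein HMGB2 by -3.55 ± 0.35, with adjusted p-values of at most 0.000155. CDKN1A was higher, at 601 ± 166 (SD, n = 3) against 165 ± 43.2 (n = 3), by 1.86 ± 0.25 (SE; 0.000421), and ASNS lower by -2.86 ± 0.49 (0.00403). Both calls held with each array left out but not with the letter b as a covariate or with only the arrays compared. GREB1 was lower by -1.68 (0.0376), to a value near background (10.0 ± 1.88, SD, n = 3), and was 0.19 on its other probe set. That call was lost with 13 of the 17 arrays left out, all but Ad E2 3, AdERb vehicle 2, AdERb TOT 1 and AdERb TOT 3, with an adjusted p of up to 0.204, and with no filter on level, only the arrays compared, and the letter b or the spike-in level as a covariate. TFF1 did not pass (-0.61, adjusted p 0.469), and AdERb E2 3 alone sets that sign: without it the value was 0.29 (0.461).

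Mitosis genes were lower with E2 by a median of -2.95, with 33 past over all genes and 36 adjusted over the list alone (8.96e-42, estimated 0.0506). Replication genes were lower by -1.56, with 20 and 26 (1.8e-17, estimated 0.114). The p53 target genes (0.21, 1 higher both over all genes and adjusted over the list alone; 0.0368, estimated 0.454) and TGF-beta target genes (0.27, 1 and 2 higher; 0.0199, estimated 0.454) were higher. Unfolded protein and integrated stress response genes were lower (-0.53, with 2 lower over all genes, and 6 lower and 1 higher adjusted over the list alone; 0.0368, estimated 0.703). In total 484 probe sets passed, 49 up and 435 down. This became 60 with the letter b as a covariate, where Ad E2 rests on Ad E2 3 alone, 86 with only the arrays compared, 152 with the spike-in level as a covariate, and 836 with the replicate block, under which the p53 and unfolded protein lists lost their calls (0.0581 and 0.0535). Quantile normalization moved the share up from 10.1% to 31.2%. Of 30 named genes 15 held with each array left out. The 484 became 157 without Ad E2 1, 158 without Ad E2 2, 1347 without Ad E2 3, 321 without AdERb E2 1 and 731 without AdERb TOT 3.

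With TOT, where no array carries the letter b, genes of cell division and DNA synthesis were lower in AdERb cells too, with an estimated adjusted p of 0.0479 for the mitosis and 0.0901 for the replication list. TPX2 changed by -4.43 ± 0.36 (SE), KIF20A by -4.33 ± 0.33, KIF2C by -4.14 ± 0.28, FOXM1 by -4.09 ± 0.38, CDCA8 by -3.71 ± 0.19, MCM5 by -3.29 ± 0.39 and PRIM1 by -3.27 ± 0.42, with adjusted p-values of at most 0.000249. Higher were CDKN1A, at 453 ± 56.2 (SD, n = 3) against 133 ± 23.8 (n = 3), by 1.77 ± 0.25 (SE; 0.000516), the stress cytokine GDF15 by 1.75 ± 0.26, RPS27L, another p53 target, by 1.47 ± 0.19 and matrix Gla protein MGP by 2.22 ± 0.44. ESR1 was lower, at 523 ± 170 against 1134 ± 119, by -1.16 ± 0.23 (0.00878), a call lost with only the arrays compared and with the spike-in level as a covariate. Of its 6 other probe sets, 2 went the opposite way (0.78 and 0.10), both at low intensity: 27.4 ± 9.13 against 15.6 ± 2.87, and 12.3 ± 1.43 against 11.4 ± 0.85. TFF1 was 3648 ± 149 against 1243 ± 216 and did not pass (1.57, adjusted p 0.0807). Among arrays left out, it passed only without AdERb E2 3 (2.87e-05). That array is not in this contrast, so the 1.57 stayed and only the shared spread changed.

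Mitosis genes were lower with TOT by a median of -3.08, with 34 past over all genes and 36 adjusted over the list alone (1.92e-42, estimated 0.0479), and replication genes by -1.74, with 21 and 29 (5.63e-19, estimated 0.0901). The p53 target genes were higher by 0.44, with 2 and 3 of 17 (0.000972, estimated 0.136). In total 638 probe sets passed, 48 up and 590 down. With the spike-in level as a covariate 152 passed, and quantile normalization moved the share up from 7.52% to 24%. Of 28 named genes 20 held with each array left out. The 638 became 279 without Ad TOT 2, 367 without Ad TOT 3, 1099 without AdERb TOT 1 and 356 without AdERb TOT 3. AdERb TOT 3 stood apart from its group: it correlated with AdERb TOT 1 and 2 at an r of 0.933 and 0.938, and they with each other at 0.986. ESR2 was 2137 on it against 4574 and 7626, and its mean log2 level of spike-in controls, 11.1, was the highest of all arrays.

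**Figure D3:**
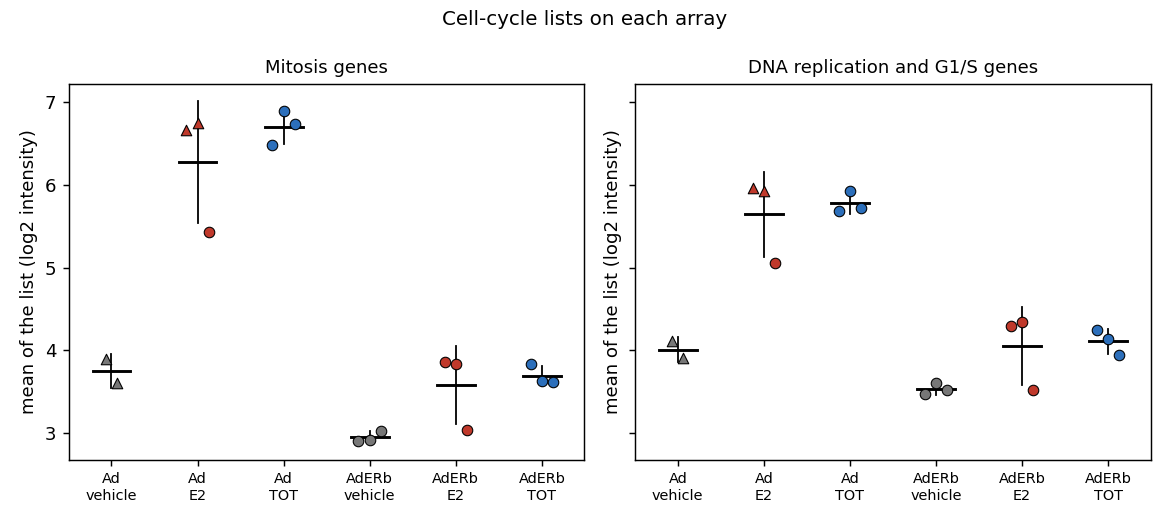
Mean log2 intensity of the mitosis list and of the DNA replication and G1/S list for the 6 groups, with a point per array (triangles carry the letter b), a bar at the mean and a line for ± 1 SD. The mitosis mean is 3.75 with vehicle, 6.28 with E2 and 6.70 with TOT in Ad cells, and 2.95, 3.58 and 3.69 in AdERb cells.

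How many genes the ligands changed in AdERb cells rests on AdERb E2 3. With all arrays limma called 0 probe sets for E2 (826 at an unadjusted p below 0.05) and 2 for TOT. Without that array it called 227 and 85, and without AdERb TOT 3 too 452 and 122. For TOT against vehicle AdERb E2 3 is not compared, so the 85 came through the shared spread alone. For E2, the 227 and 452 rest on AdERb E2 1 and 2, of which AdERb E2 1 had the 3' bias given below. TOT lowered BAK1 by -1.83 ± 0.26 (SE; adjusted p 0.0296) and the actin gene ACTB by -0.52 ± 0.07 (0.0296), the only probe sets of 12721 that passed, both down. BAK1 passed only without Ad E2 2, Ad E2 3, AdERb vehicle 3, AdERb E2 3, AdERb TOT 1 or AdERb TOT 3 among fits leaving out an array, and otherwise reached 0.137. ACTB passed only without Ad E2 1, 2 or 3, AdERb vehicle 2, AdERb E2 2 or 3, or AdERb TOT 1 or 3, and otherwise reached 0.148. Neither passed with only the arrays of AdERb cells or without a trend in the variance prior, nor ACTB after quantile normalization. TFF1 was 1050 ± 88.9 (SD, n = 3) with vehicle, 2148 ± 1467 with E2 and 3648 ± 149 with TOT, and neither change passed (0.62, adjusted p 0.908, and 1.80, 0.226). Both rest on AdERb E2 3, where TFF1 was 465 against 3158 and 2822: without that array TFF1 rose by 1.51 with E2 (0.000689) and by 1.80 with TOT (5.29e-05). For TOT the 1.80 stayed and only the shared spread changed. ESR1 (-0.73, 0.495, and -1.22, 0.0976) and MYC (1.28, 0.541, and 1.12, 0.527) did not pass either. Without AdERb E2 3, MYC passed with E2 (1.85, 0.0214) and ESR1 with TOT (0.0205), and ESR1 with TOT also passed without AdERb TOT 1 (-1.48, 0.037). Genes of DNA synthesis and cell division passed without AdERb E2 3 too. With E2, RRM2 rose by 5.385 (1.55e-07), PTTG1 by 4.06 (6.63e-06) and UBE2C by 3.52 (2.39e-05). With TOT they rose by 4.36 (6e-07), 3.305 (2.22e-05) and 3.11 (2.88e-05). With all arrays none of the 3 passed with either ligand.

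For E2 in AdERb cells the smallest adjusted p was 0.168. AdERb E2 1 stood out by a 3' bias, which can be a sign of degraded RNA: the log2 difference of the 3' and 5' control probe sets was 3.63 for ACTB and 2.08 for GAPDH, against at most 2.02 and 0.92 on other arrays. Without it the count stayed 0. Against vehicle, TOT had 946 at an unadjusted p below 0.05. TOT against E2 gave 0, with 262 unadjusted, a share under 0.05 of the 12721 and so no excess. The 0 for E2 became 227 without AdERb E2 3, 14 without AdERb TOT 3, 1, 2 and 5 without AdERb vehicle 1, 2 and 3, 1 without Ad E2 3 and 1 without AdERb E2 2. The 2 for TOT became 85 without AdERb E2 3, 16 without AdERb TOT 1, 18 without AdERb TOT 3, 8 without AdERb vehicle 3, 5 without Ad E2 3, 1 without Ad E2 1, AdERb vehicle 1 or AdERb E2 2, and 0 without either Ad vehicle array, any Ad TOT array, AdERb E2 1 or AdERb TOT 2. The 0 for TOT against E2 became 15 without AdERb TOT 3, 9 without AdERb E2 3, and 1 without AdERb E2 2 or AdERb TOT 1. Quantile normalization gave 25 for TOT, 28% of them up. No gene was TOT-preferential, E2-preferential or changed the same way with both in AdERb cells, but without AdERb E2 3 limma called 3 E2-preferential and 44 changed the same way. Without AdERb TOT 3 it called 4 TOT-preferential, 1 E2-preferential and 1 changed the same way, and 1, 2 and 4 genes changed the same way without AdERb vehicle 1, 2 and 3.

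Gene lists in AdERb cells passed only with the preset correlation, and none with the estimated correlation. With E2 they were mitosis (median 0.23; 5.97e-06, estimated 0.475), replication (0.32; 7.8e-05, 0.475), estrogen-induced (0.25; 0.0174, 0.539), estrogen-repressed (-0.64; 0.00317, 0.475), ribosome biogenesis (0.39; 0.0448, 0.539), luminal (-0.22; 0.00258, 0.271) and actin genes (-0.53; 2.52e-05, 0.238). Adjusted over the list alone, 9 mitosis genes rose with E2, 2 actin genes fell, and 1 estrogen-repressed gene rose and 2 fell. With TOT they were mitosis (0.32; 2.47e-08, 0.369), replication (0.32; 1.11e-05, 0.369), estrogen-induced (0.40; 3.15e-06, 0.339), estrogen-repressed (-0.48; 1.11e-05, 0.21), p53 (-0.29; 0.0172, 0.339), luminal (-0.41; 0.00229, 0.21) and actin genes (-0.59; 4.22e-05, 0.21). Adjusted over the list alone, 5 mitosis, 3 replication and 2 estrogen-induced genes rose with TOT, 5 estrogen-repressed and 2 actin genes fell, and luminal genes went both ways, with 3 up and 8 down. Between TOT and E2, estrogen-induced (0.076; 0.00805, 0.938) and estrogen-repressed genes (-0.38; 0.0447, 0.938) passed, and both medians turned without AdERb E2 3 and AdERb TOT 3 (to -0.076 and 0.16). The correlation of the E2 and TOT changes was 0.781, against a simulated mean of 0.478 and a 95% range from -0.211 to 0.884, and the covariance 0.1042 against a simulated mean of 0.0435 and a range from -0.0123 to 0.1447. Both lay inside the ranges of unchanged groups that share vehicle arrays. The correlation was 0.64 without AdERb E2 3 and AdERb TOT 3.

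Whether a ligand acts differently in AdERb cells was tested as the difference of its effects. The E2 effect on CDCA8 was lower in AdERb than in Ad cells, by -3.36 ± 0.29 (SE; adjusted p 3.32e-05), as it was for cyclin CCNA2 by -3.19 ± 0.25, the kinase PLK1 by -2.77 ± 0.23 and KIF2C by -3.66 ± 0.42. ACKR3 fell with E2 in Ad cells by 1.86 and FBN2 by 1.43, and the differences of the effects were 1.65 ± 0.24 and 1.34 ± 0.19. Their vehicle level was already low in AdERb cells. For TOT the differences were -3.44 ± 0.29 for CDCA8, -3.29 for CCNA2, -3.45 for PLK1, -3.98 ± 0.42 for KIF2C, 1.89 ± 0.24 for ACKR3 and 1.38 ± 0.19 for FBN2, and all of these passed with each array left out. For TFF1 the difference did not pass for E2 (-2.94, adjusted p 0.244) or TOT (-0.76, 0.806), but without AdERb E2 3 that for E2 was -2.04 and passed (0.00193).

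Mitosis genes had a median difference of -1.92 for E2 (8 past over all genes, 25 adjusted over the list alone; 6.33e-48, estimated 0.0312) and -2.22 for TOT (10 and 27; 2.01e-46, estimated 0.035). Replication genes had -1.11 for E2 (1 and 7; 5.62e-19, estimated 0.0901) and -1.12 for TOT (2 and 14; 4.9e-19, estimated 0.0893). The mitosis list mean in AdERb vehicle cells, 2.95 on the log2 scale, lay near the array medians. A ligand's rise from there may be understated, so the mitosis differences are not exact in size and may be overstated. For E2, estrogen-induced (-0.65, 1 lower adjusted over the list alone; 6.22e-07, estimated 0.316), unfolded protein (-0.39; 0.00153, estimated 0.475), TGF-beta (0.26; 0.0121, estimated 0.316) and actin lists (-0.35, 1 lower adjusted over the list alone; 0.00984, estimated 0.316) also passed, as did the actin list for TOT (-0.72; 0.000912, estimated 0.219). The tests called 35 probe sets for E2, 4 up and 31 down, and 60 for TOT, 4 up and 56 down. Among the 3178 with a mean above 6 on the log2 scale they called 0 and 2. Beside that 0, limma had 129 at an unadjusted p below 0.05, a share under 0.05. The 35 became 21 without Ad vehicle 1 and 191 without Ad E2 3, and the 60 became 138 without Ad E2 3.

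**Figure D4:**
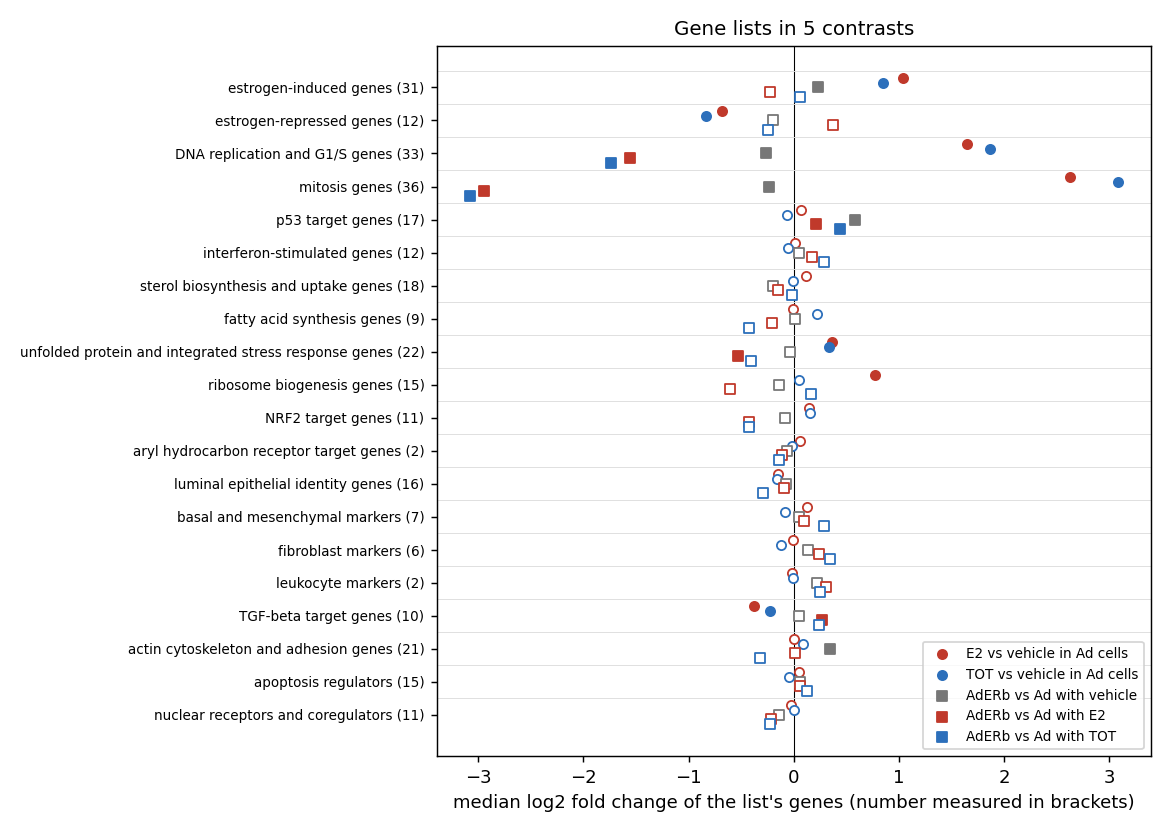
Median log2 change of each of the 20 gene lists in 5 contrasts, with circles for a ligand against vehicle in Ad cells and squares for AdERb against Ad cells, filled where the list passed with the preset correlation. Mitosis genes stand at 2.62 with E2 and 3.08 with TOT in Ad cells, and at -2.95 and -3.08 for AdERb against Ad with the same ligands.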

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

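The tests of the spike-in level and of the letter b in this part were chosen only after the results were seen. The interaction tests of the ligand effects were not.

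The effect of E2 differed between AdERb and Ad cells in 35 probe sets by the test of the difference itself. Among the 3178 with a mean above 6 on the log2 scale it differed in 0. There, 129 had an unadjusted p below 0.05 in limma, a share under 0.05. Among named genes, the log2 difference was positive for ACKR3 (1.65), FBN2 (1.34) and STON1 (1.01). It was negative for KIF2C (-3.66), PRIM1 (-3.39), CDCA8 (-3.36), PBK (-3.30), KIF4A (-3.25), KIF20A (-3.21), CCNA2 (-3.19), ASPM (-2.82), PLK1 (-2.77) and NUPR1 (-2.65). The calls of PBK and KIF20A were lost without Ad vehicle 1 (adjusted p 0.0677) and Ad vehicle 2 (0.078). Those of ASPM and NUPR1 were lost without any vehicle array or Ad E2 1 or 2, and that of ASPM also without AdERb E2 1 or 2 (up to 0.115 and 0.117). STON1 passed only without Ad vehicle 2 or Ad E2 3, and otherwise reached 0.267. With only the arrays compared STON1, PRIM1, KIF20A and ASPM did not pass, nor NUPR1 after quantile normalization. PRIM1 passed only without Ad E2 3, Ad TOT 2 or 3, or AdERb E2 2 or 3, and otherwise reached 0.191. The count was 21 without Ad vehicle 1 and 191 without Ad E2 3. The lists that differed were mitosis (median -1.92), replication (-1.11), estrogen-induced (-0.65), unfolded protein and integrated stress response (-0.39), actin (-0.35) and TGF-beta target genes (0.26), and only the mitosis list passed with the estimated correlation.

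The effect of TOT differed in 60 probe sets, in 138 without Ad E2 3, and in 2 of the 3178 with a mean above 6. The difference was positive for ACKR3 (1.89), SERPINI1 (1.43) and FBN2 (1.38), and negative for KIF2C (-3.98), ASPM (-3.64), KIF4A (-3.53), PLK1 (-3.45), CDCA8 (-3.44), DLGAP5 (-3.35), KIF20A (-3.32), CCNA2 (-3.29), ATAD2 (-3.22), PBK (-3.20), PRIM1 (-3.19) and GINS1 (-2.32). PBK lost its call without Ad vehicle 1 (0.0551). SERPINI1 lost it without either Ad vehicle array, Ad TOT 1 or 2, AdERb vehicle 1 or 3, or any AdERb TOT array (up to 0.163). PRIM1 passed only without any of the Ad E2 arrays or AdERb E2 2 or 3 (otherwise up to 0.18), and GINS1 only without any of the Ad E2 arrays or AdERb E2 3 (otherwise up to 0.201). SERPINI1 did not pass with the letter b as a covariate, nor PRIM1 and GINS1 with an offset before log2. The lists were mitosis (-2.22), replication (-1.12) and actin genes (-0.72), and again only mitosis passed with the estimated correlation.

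The hybridization spike-in controls, which enter no comparison, also differed. Their mean over 18 probe sets was higher in AdERb arrays by 0.88 on the log2 scale, at 10.6 ± 0.35 (SD, n = 9) against 9.71 ± 0.557 (n = 8), with an exact two-sided permutation p of 0.00226 over 24310 splits. The permutation took no account of ligand or of the letter b, which only Ad arrays carry. Ad arrays with the letter lay between 9.22 and 9.71, and those without it between 9.20 and 10.8. The test therefore does not part the virus from the letter. A higher spike-in level can go with less labelled cRNA on an array or with its scaling, so this level was set against the cell division genes.

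Mitosis and DNA replication genes were lower in AdERb than in Ad cells under both ligands with the preset correlation, but with the estimated correlation only mitosis with TOT passed (adjusted p 0.0479), against 0.0506 with E2 and 0.114 and 0.0901 for replication with E2 and TOT. The difference of the array means of both lists was -2.27, and -1.72 ± 0.16 (SE) with the spike-in level in the model, which argues against that level as the whole cause. With TOT, where no array carries the letter b, it was -2.37 ± 0.29, which argues against the letter for that part. For E2 the letter stays open, since only Ad E2 replicate 3 lacks it among the Ad E2 arrays: it lay 1.17 above the highest AdERb E2 array, a value from 1 array. The expression of estrogen receptor beta, which the design set out to change, may be a cause and was not tested. The labels part no groups by dose of virus, and no virus with another receptor was used. ESR2 ranged from 1801 to 9679 among AdERb arrays, but its level was not set against these lists.

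Both lists were higher with either ligand than with vehicle in Ad cells: the difference was 2.25, and 2.40 ± 0.16 (SE) with the spike-in level in the model, which argues against that level as the cause. Between E2 and vehicle arrays that all carry the letter it was 2.47 ± 0.24, which argues against the letter for E2. For TOT, no array carries the letter and both vehicle arrays do, so the letter can be estimated only through E2, where the 1 array that lacks it lay at -1.09 against those with it. That array, Ad E2 3, had a spike-in level of 10.8, against 9.35 and 9.22 on Ad E2 1 and 2. The -1.09 therefore cannot part the letter from the signal of that array. With the letter as a covariate, TOT against vehicle in Ad cells gave 498 probe sets, 451 of them up, and medians of 4.23 for mitosis genes and 2.97 for DNA replication and G1/S genes. This estimate rests on 1 array, so for TOT the letter stays open, and an effect of TOT itself may be the cause.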

How the results depend on the processing

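The spike-in level as a covariate, leaving out both AdERb E2 replicate 3 and AdERb TOT replicate 3, comparisons within the letter, and probe sets with a mean above 6 were chosen only after the results were seen. For 587 results on named genes, 17161 values under alternatives gave 15730 on the same side of the threshold in the same direction, 990 no longer past it, 428 newly past it and 13 in the opposite direction. The cause was not tested, except that fewer probe sets or arrays were tested where a filter or omission took them out: 22215 probe sets without the filter on level, 6771 with the stricter one and 3178 with a mean above 6. An array left out of a group outside the contrast can act only through the shared spread.

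With each array left out in turn, changed probe sets ranged from 114 to 762 for E2 against vehicle in Ad cells (295 with all arrays), from 201 to 498 for TOT against vehicle in Ad cells (394), from 41 to 286 for TOT against E2 in Ad cells (116), from 0 to 227 for E2 in AdERb cells (0), from 0 to 85 for TOT in AdERb cells (2) and from 0 to 15 for TOT against E2 in AdERb cells (0). They ranged from 10 to 43 for AdERb against Ad with vehicle (15), from 157 to 1347 with E2 (484) and from 279 to 1099 with TOT (638), and from 21 to 191 and from 40 to 138 for the differences of the E2 and TOT effects (35 and 60). In Ad cells, TOT-preferential genes ranged from 19 to 60 (41), E2-preferential ones from 3 to 118 (17) and those changed the same way from 62 to 208 (123). In AdERb cells, where all are 0, they ranged up to 4, 3 and 44. Leaving out an Ad vehicle array leaves 1 there, which is then assumed to vary like the other groups.

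Estimated array weights gave 1120 probe sets for E2 and 778 for TOT against vehicle in Ad cells, 1111 for TOT against E2 in Ad cells, 787, 1664 and 2577 for the same contrasts in AdERb cells, 100, 3418 and 6575 for AdERb against Ad with vehicle, E2 and TOT, and 98 and 353 for the differences of the E2 and TOT effects. They gave 122 TOT-preferential, 265 E2-preferential and 317 jointly changed genes in Ad cells and 415, 304 and 183 in AdERb cells. The weights did not converge and gave AdERb TOT replicate 2 a weight of 34.9, against 0.115 to 2.34 for the others, and what moved these counts was not tested.

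With the letter b as a covariate there were 764 for E2 in Ad cells, 1 for E2 and 5 for TOT in AdERb cells, 53 and 60 for AdERb against Ad with vehicle and E2, 192 and 276 for the differences, 4 E2-preferential and 251 jointly changed genes in Ad cells. Within arrays that share or lack the letter, E2 in Ad cells gave 764 and AdERb against Ad with E2 gave 60, the same counts as with the covariate. Arrays that lack it leave Ad E2 replicate 3 alone for Ad E2, so these are not further tests. With only the arrays of the cells compared there were 527 for E2 and 217 for TOT against E2 in Ad cells. For TOT in AdERb cells there were 0, with 604 in limma at an unadjusted p below 0.05, a share under 0.05. There were 86 for AdERb against Ad with E2, 21 and 140 for the differences, and 66 TOT-preferential, 52 E2-preferential and 185 jointly changed genes in Ad cells.

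With the spike-in level as a covariate there were 846, 668 and 219 for E2, TOT and TOT against E2 in Ad cells, 2 and 10 for E2 and TOT in AdERb cells, 152 for AdERb against Ad with E2 and 152 with TOT, 76 and 113 for the differences, and 66 E2-preferential and 273 jointly changed genes in Ad cells. Without both AdERb E2 replicate 3 and AdERb TOT replicate 3 there were 650, 616 and 269 in Ad cells, 452, 122 and 57 in AdERb cells and 87 for AdERb against Ad with vehicle. TOT-preferential, E2-preferential and jointly changed genes were then 73, 62 and 224 in Ad cells and 6, 26 and 57 in AdERb cells, and the correlation of the E2 and TOT changes in AdERb cells was 0.64 against 0.781.

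Among probe sets with a mean above 6 there were 71, 79 and 13 for E2, TOT and TOT against E2 in Ad cells, 1 and 11 for E2 and TOT in AdERb cells, 238 and 241 for AdERb against Ad with E2 and TOT, 0 and 2 for the differences of the E2 and TOT effects, and 6 TOT-preferential, 5 E2-preferential and 23 jointly changed genes in Ad cells. The lower counts lie where fewer probe sets were tested. Beside the 0, limma had 129 at an unadjusted p below 0.05 among these 3178 probe sets, a share under 0.05. The stricter filter gave 74 for TOT against E2 in Ad cells and 9 for AdERb against Ad with vehicle. Quantile normalization gave 3 for E2 and 25 for TOT in AdERb cells, 51 for AdERb against Ad with vehicle and 2 jointly changed genes in AdERb cells. For TOT in AdERb cells, no trend in the variance prior gave 0 (963 unadjusted in limma) and a minimum of 1.5-fold gave 1. No filter on level and an offset before log2 left every count within 1.5 times.

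The replicate block gave 447 for E2 in Ad cells, 5 for TOT in AdERb cells, 836 for AdERb against Ad with E2 and 1826 with TOT, and left every other count within 1.5 times. For AdERb against Ad with E2 the block ended the calls of the p53 and unfolded protein lists and changed no other list call. Over all contrasts under the block, the estrogen-repressed list passed in 3 contrasts and the fibroblast list in 1. Where groups share 3 numbers, between 2 and 4 of the 6 arrays correlated best with an array of their own number. For AdERb against Ad with E2 it was 3 of the 6. By the labels, the samples share only a number in every contrast. Apart from AdERb against Ad with E2, correlations within a pair lay between -0.419 and 0.54.

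Of the 11 contrasts, estrogen-induced genes passed in 7, repressed in 5, replication in 9, mitosis in 10, p53 in 5, unfolded protein in 4, ribosome biogenesis in 3, luminal in 2, basal in 1, TGF-beta in 4 and actin genes in 5. With the estimated correlation, mitosis passed in 5, replication in 2, p53 in 1 and the others in 0. With the letter b as a covariate the counts were 3 for repressed, 3 for sterol, 2 for basal, 2 for actin and 1 for apoptosis genes. With the spike-in level they were 5 for ribosome biogenesis and 2 for apoptosis genes, without the pair AdERb E2 replicate 3 and AdERb TOT replicate 3 they were 1 for sterol and 1 for fatty acid genes, with quantile normalization 2 for unfolded protein genes, and with the mean over a gene's probe sets 5 for ribosome biogenesis, 1 for fatty acid and 1 for fibroblast genes.

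Directions turned in few results. For TOT against E2 in AdERb cells, the medians of estrogen-induced and repressed genes turned to -0.076 and 0.16 without AdERb E2 replicate 3 and AdERb TOT replicate 3. For AdERb against Ad with vehicle, replication genes turned to 0.60 and mitosis genes to 0.50 with the letter b as a covariate, and replication genes to 0.17 with the spike-in level. On another probe set, CPM was -0.18 for TOT against vehicle and -0.12 for TOT against E2 in Ad cells, RARA -0.73 for TOT against vehicle in Ad cells, PCLAF 0.28, GREB1 0.19 and LPP 0.23 for AdERb against Ad with E2, and ESR1 0.78 and 0.10 for AdERb against Ad with TOT. These GREB1 and ESR1 probe sets had a low signal, at 8.39 for GREB1 in AdERb E2 cells and 27.4 and 12.3 for ESR1 in AdERb TOT cells. With the letter b as a covariate, GREB1 was 2.10 for TOT against vehicle in Ad cells and -1.89 for the difference of the TOT effect. With array weights, TRIB3 was 0.83, ERBB3 0.77 and BIK 1.14 for TOT against E2 in AdERb cells.

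Other splits of the 6 arrays of a contrast into groups of 3 number 10 with the real one, too few for a share under 0.05. For TOT against E2 in Ad cells the real split gave 116 and the highest other 54, and 1 split, the real one, reached as many. For AdERb against Ad the real and highest other values were 484 and 22 with E2 and 638 and 0 with TOT, with 1 split each. Among the 4 splits with E2 that part every replicate pair, the other 3 gave 0, and the rest gave at most 22. In AdERb cells the values were 0 and 4 for E2 (10 of 10 splits reached as many), 2 and 14 for TOT (2 of 10) and 0 and 100 for TOT against E2 (10 of 10). The 100 points to a structure of these samples. The split that exchanges AdERb E2 3 and AdERb TOT 3 gave 96. ESR2 was 9679 on AdERb E2 3 and 2137 on AdERb TOT 3. It was 2520 and 2160 on AdERb E2 1 and 2, and 4574 and 7626 on AdERb TOT 1 and 2. Each of the 2 arrays thus lay nearer to the other group in ESR2. TFF1 on AdERb E2 3, at 465, lay far below the other arrays of both groups, at 2822 to 3752. Whether these arrays were exchanged was not tested and stays open.

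Signal over background limits the fold changes. The mitosis list mean of 2.95 on the log2 scale in AdERb vehicle cells lies near the array medians, which are between 7.4 and 9.18 on the linear scale, so a further fall there would not be seen. A ligand's rise from that level may be understated, and the differences of the ligand effects between AdERb and Ad cells overstated.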

Other observations

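The test of the genes raised by E2 in this part was chosen before its result was seen. The tests of AdERb E2 replicate 3 were chosen only after its values were seen.

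Some single genes outside the cell cycle are given here with their values. In Ad cells NUPR1 was at 8.07 ± 0.02 (log2 mean ± SD, n = 3) with E2 against 5.80 ± 0.65 (n = 3) with TOT, PCK2 at 7.43 ± 0.16 against 5.38 ± 0.53, and ASNS at 9.34 ± 0.57 against 7.69 ± 0.69. NUPR1 and PCK2 passed in TOT against E2 (adjusted p 0.00245 and 0.00183), and ASNS did not (0.186). MGP was at 8.39 ± 0.53 with E2 and 6.12 ± 0.25 with TOT in Ad cells, a call lost without Ad E2 1 or 2 or any Ad TOT array (up to 0.119) and with the letter b as a covariate. In AdERb cells with TOT it was at 8.35 ± 0.52. ACTG2 stood at 787 ± 229 in AdERb vehicle cells but at 155 ± 198 with E2 and 132 ± 104 with TOT, log2 changes of -3.17 and -2.97 that did not pass (limma adjusted p 0.317 and 0.197).

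A hypothesis was that estrogen receptor beta lowers genes raised by E2 beyond the cell division lists. Of the 155 genes raised by E2 in Ad cells, 114 are in neither list. Their median log2 change for AdERb against Ad with TOT was -1.01, with quartiles of -2.10 and -0.31. Of the 114, 97 (85.1%) were lower, against 50.2% of all 7772 genes, and 56 passed as lower and 2 as higher. The fixed list of estrogen-induced genes did not move in that contrast (median 0.057, 16 of 31 positive, 0 past the threshold, camera adjusted p 0.663). The outcome therefore fits the hypothesis only for genes chosen by their rise with E2 here, and genes that follow the cell cycle without being on a list may add to it, as the -1.01 cannot separate them.

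AdERb E2 replicate 3 stood apart from the other AdERb E2 arrays. TFF1 was 465 on it against 3158 and 2822, and the mitosis list mean was 3.04 against 3.86 and 3.84. Its score, the mean of genes raised by both ligands in Ad cells minus the mean of those lowered, lay 1.51 SDs above the AdERb vehicle mean. It may be a sample that did not receive E2, which stays open, because its TFF1 (8.86 on the log2 scale) and ESR2 (12.2) lay away from the vehicle arrays (10.03 ± 0.12 and 9.79 ± 0.16, SD, n = 3). The spike-in level predicted a gap of -0.20 in that score and left -0.91 ± 0.33 (SE) beyond it, which argues against array signal as the whole cause, and no biological explanation was tested.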
